A study of Mus musculus with 2 samples.

How the data were processed

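DNase-seq was measured in 2 libraries from female B6CASTF1/J mice at 25 days, whose tissue type the labels give as layer of hippocampus, without naming the layer, and whose description they give as hippocampus. The labels give the libraries as biological replicates 1 and 2 from separate tissue samples and give both the same donor entry. Whether that entry stands for an animal or for the strain, and so whether the libraries came from different animals, is not stated, and the spread between them may be technical in part. Both form 1 group, and no paired analysis was possible because there is no second group to pair with. All coordinates are on mm10, per the labels, and are printed counting from 1.

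The authors deposited 4 files per library, and the deposited description states that each was made from the alignments of that library alone. The aligner, the peak caller and the filters are not given in the sources used here. The deposited signal value of each peak was the unit of peak strength, and its scaling is not stated: all values of a library were whole multiples of 1 step (to a tolerance of 0.05 of a step). Signals of the libraries are therefore set side by side as deposited, without further normalisation. The main peak list was the one of the 2 per library with the narrower peaks or, at equal width, fewer peaks. Tested on the files, each of its peaks holds at least 1 base with a deposited p-value of the cut rate, given as a false discovery rate (FDR), of 0.001 or less, and each peak of the longer list 1 base at 0.05 or less. The cut-rate files list the deposited p-value (FDR) per stretch of bases up to 0.05 only. The footprint files carry a deposited FDR, a kind of p-value, that is constant at 0.01, so footprints could not be ranked. Alignments, read-depth normalised coverage tracks and all other files that the deposited description names were not used here. Depth per library is unknown from the files used, and the precision of single values is limited by having 2 libraries.

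Genes came from GENCODE M21 on GRCm38.p6, the same build as mm10, and all peak ends lay within its chromosome lengths. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 served to check the overlap counts. A shared region is a connected set of overlapping peaks of both libraries, joined at an overlap of 1 bp or more. Chance overlap came from 100 random placements of the peaks on their own chromosomes. Regions were assigned, in this order, to promoters (500 bp either side of a start of a protein-coding or long noncoding RNA gene), exons, introns and intergenic sequence, and compared with 100 random placements. A promoter is called open when peaks of both libraries lie within 500 bp of any annotated start of the gene. Distal regions are shared regions outside all promoter windows and were counted from 50 kb before to 50 kb after each gene.

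The comparisons, tests, gene lists, motifs, named genes and main alternatives were chosen before the data were examined. The 31 lists cover pan-neuronal, excitatory hippocampal neuron, CA1, CA2 and CA3, dentate granule cell, neurogenesis, GABAergic interneuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, vascular, choroid plexus, activity-regulated, forebrain factor, Hox, midbrain, hindbrain and spinal cord, monoaminergic and cholinergic, synaptic, long-term potentiation and CREB, circadian, imprinted, X-inactivation escape and housekeeping genes. The remaining lists, of cells foreign to the tissue, are hepatocyte, striated muscle, blood cell, male germ cell, keratinocyte, photoreceptor and lens, and olfactory receptor genes. Some genes stand in more than 1 list, such as Dlg4 and Camk2a. For each list the share of open promoters was compared with 10000 random lists of other protein-coding genes matched on decile of the CpG observed to expected ratio. That ratio was taken in 1000 bp around the outermost start of a gene only, whereas any annotated start could make the gene open. The number of starts per gene was not matched. The mean number of distal regions was compared with lists matched on decile of gene length. Percentile p-values were two-sided and adjusted over the 31 lists by the Benjamini-Hochberg method, and a list was called at an adjusted p below 0.05. Genes and windows are not replicates, so every such p describes these libraries, not other animals.

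The 32 motifs, written as consensus sequences, were sought on both strands in 200 bp windows centred on distal regions and in a window 1000 bp to a random side that touched no peak. For footprints, those shared at 50% of the shorter one and lying in shared regions were widened by 8 bp and compared with a window of equal width 100 bp away in the same region and outside footprints. Both comparisons used the McNemar exact test, two-sided, adjusted over 32 motifs, and ratios that rest on few windows carry an exact binomial interval, conditional on the sum of both counts. Open promoters of X and autosomal genes were compared by the Fisher exact test, and by 10000 draws of autosomal genes matched on CpG decile.

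Genes were named by a rule: in each list the 2 members with the most distal regions and the first 1 in alphabetical order without a promoter peak, the 10 genes of the genome with the most distal regions, the 5 strongest shared regions, Xist, and all open or all other members where these were 5 or fewer. Some genes that the rule names are not reported here. Genes named outside the rule are said to have been chosen after their values were seen.

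Alternatives were the longer peak lists, the stronger 50% of each list, equal numbers of peaks, overlaps of 50% of both peaks, a promoter window of 2000 bp, 10 kb around genes, unmatched random lists, windows of 100 bp, random genomic windows matched on GC content in bins of 2 points, footprints without widening, an overlap of footprints by 1 bp, an FDR of 0.005 for cut rates, and each library on its own. Added after the data were seen were basic transcript starts only, X against autosomes without olfactory receptor genes, the correlation with the longer lists, motifs of peaks found in a single library within bins of GC content and without 100 kb bins holding 10 or more such peaks, and the forebrain factor list without Tcf4, set against random lists that each lost their member with the most peaks of replicate 1. Added as well were pairs of footprint and background windows within 2 points of GC content, and the Hox and olfactory receptor lists moved along the order of protein-coding genes by each of the 21937 possible steps, which keeps neighbours together but matches neither length nor CpG content. A count was taken as changed beyond 1.5 times its value, a Jaccard index beyond 5%, and a correlation beyond 0.05. These last limits were set by judgement.

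The methods were tested on simulated data. In the comparison of gene lists with matched random lists, run on 20000 simulated genes, 2.67% of 300 lists of 20 genes without an effect had a p under 0.05, and 93% of 300 lists with 95% open genes did. In the motif comparison on 10000 simulated windows, all of 200 windows with a planted motif were found (100%) and 0 of 31 other motifs were called. The planted sequence was an exact match of the CTCF consensus, so finding it was fixed in advance and checks the code only. Simulated windows and their background had the same base composition. The simulation therefore says nothing of calls that arise from a difference in GC content. In the overlap comparison on 5000 simulated intervals, counts differed from bedtools by 0.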

Results

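DNase-seq, which maps the chromatin that the nuclease DNase I can reach, was applied to tissue labelled as a layer of hippocampus, the layer not being named, of female B6CASTF1/J mice, a hybrid of a laboratory strain and the wild-derived CAST strain, at 25 days of age. The 2 libraries were biological replicates 1 and 2 of 1 group, so no difference between conditions could be tested, and every value describes these 2 libraries. Peaks, footprints and a signal value for each peak were given on the mouse genome build mm10. Sequencing depth was unknown, because the files used here hold no tag counts, so no interval for counting error is given.

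Replicate 1 had 61466 peaks covering 11.7 Mb, with a median width of 180 bp, and replicate 2 had 50379 peaks covering 10.3 Mb, with a median width of 200 bp. Peaks of both replicates overlapped in 37119 shared regions, which held 62.9% of the peaks of replicate 1 and 76.0% of those of replicate 2. Peaks placed at random on the same chromosomes overlapped in 0.770% on average and 0.854% at most over 100 placements. The Jaccard index of the covered bases was 0.434. With the longer peak lists, called at a false discovery rate of 0.05, there were 61152 shared regions, and among the stronger 50% of each list there were 21395.

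Across the shared regions the peak signal of both libraries had a Spearman rank correlation of 0.821, computed across regions, which are not independent replicates. Signal was higher in replicate 1 at 96.5% of the regions, with medians of 2.49 and 0.990 and a median log2 ratio of 1.19 (interquartile range 0.73 to 1.70). The correlation describes the order of regions and leaves the difference in level untouched. Of the peaks found in replicate 1 alone, 22828 in number, 45.8% overlapped a peak in the longer list of replicate 2. Of the 12071 peaks found in replicate 2 alone, 48.1% overlapped a peak in the longer list of replicate 1.

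**Figure D1:**
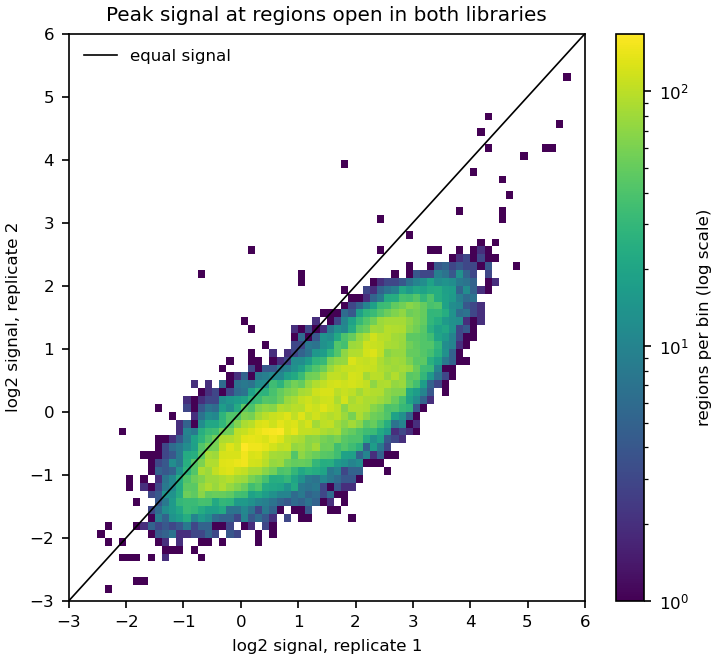
Peak signal on the log2 scale in replicate 1 (x axis) and replicate 2 (y axis) at the 37119 shared regions, with colour giving the number of regions per bin on a log scale. Most regions lie below the line of equal signal, as 96.5% had the higher value in replicate 1.

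Promoters held the largest group of shared regions, and their peaks were the strongest and widest. Of the shared regions, 41% overlapped a window of 500 bp either side of an annotated transcription start, 13.2 times the share of randomly placed regions, which was 3.10%. Introns held 25.0% of the regions and intergenic sequence 28.6%, which were 0.648 and 0.538 times the random shares, and exons held 5.37%, or 1.05 times. Median promoter signal was 3.33 in replicate 1 and 1.41 in replicate 2, against 1.87 and 0.855 in introns. Taking all peaks of a single library, the promoter share was 36.3% in replicate 1 and 35.3% in replicate 2.

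The strongest shared regions lay at a ribosomal RNA gene, in exonic and intronic sequence, and between genes. First by the mean of its signal ranks in both replicates was a region on chromosome 17 (39846781 to 39846920), with 53.7 in replicate 1 and 38.7 in replicate 2, which overlaps the ribosomal RNA gene CT010467.1. Ribosomal RNA genes exist in repeated copies, so tags there cannot be assigned to 1 copy. The other 4 of the 5 strongest regions also lay far above the median signals of 2.49 and 0.990. Whether their tags come from repeated sequence was not tested, and no list of artefact regions was applied here. It was followed in that order by an exon of Lars2, a mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123461881 to 123462140; signal 48.9 and 22.9). After it in the same order stood exonic sequence within Kpna1, an importin gene (chromosome 16, 35981661 to 35981840), with signal 41.1 and 18.5. The antisense gene Gm15564 also lies there, and the exon was not assigned to either gene. The remaining members of the 5 strongest were an intergenic region nearest to Igf2bp3 (chromosome 6, 49236421 to 49236620; 44.5 and 17.6) and an intron of Il31ra (chromosome 13, 112578161 to 112578320; 31.2 and 17.3).

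Of 21938 protein-coding genes, 11890 (54.2%) had a peak of both replicates within 500 bp of a transcription start and are called open here. Replicate 1 alone gave 60.2% and replicate 2 alone 54.8%. Of 10155 long noncoding RNA genes, 18.0% were open. CpG content of the promoter went with opening, from 4.60% of genes in the lowest decile of the observed to expected CpG ratio to 91.9% in the highest. Each of the 31 gene lists was therefore compared with 10000 random lists matched on that decile, in a two-sided permutation test adjusted over the 31 lists.

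Promoters of genes used by all neurons, by synapses and by recently active neurons were open more often than those of genes matched on CpG content at the outermost start. Of the pan-neuronal list 19 of 20 genes were open, all but Dlg4, a postsynaptic scaffold gene with a peak in replicate 1 only. Open members included the splicing regulator genes Rbfox1 (chromosome 16, 5885355 to 7411526; promoter signal 1.71 and 0.953 in replicates 1 and 2) and Rbfox3, whose product is the neuronal marker NeuN (chromosome 11, 118489762 to 118911597; 0.684 and 0.968). Among activity-regulated genes, which neurons transcribe after stimulation, 27 of 28 were open, including Btg2 (5.26 and 2.08) and Fosb (6.45 and 2.15), and only Inhba lacked a peak in replicate 2. Egr1, chosen after its values were seen, had the highest promoter signal of that list in replicate 1 (13.4, with 3.59 in replicate 2). Of the synaptic adhesion and scaffold list 27 of 32 were open, among them Cntnap2 (1.54 and 0.983) and Dlg2 (6.57 and 2.86), while genes with a peak in replicate 1 only included Dlgap3, Shank1, Homer2 and Dlg4. Of the housekeeping list, genes active in nearly all cells, 25 of 26 were open, with Actb at 8.76 and 3.38, and Reep5 was the exception. These lists were above random lists at 95% against 61.5% for pan-neuronal genes (adjusted permutation p 0.000886), 96.4% against 75.6% for activity-regulated genes (0.00387), 84.4% against 63.8% for synaptic genes (0.00954) and 96.2% against 76.9% for housekeeping genes (0.0115). The value 0.000886 is what adjustment makes of 0.0002, the smallest p that these permutations can give. With basic transcript starts only, the pan-neuronal share was 80% and the synaptic share 75%, and both calls ended, with adjusted p over 6 alternatives from 0.000775 to 0.0555 and from 0.000775 to 0.140. Random lists were not matched on the number of annotated starts, and its part in these calls was not tested.

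Promoters of developmental genes for other body regions, and of other organs, were mostly closed. Of the Hox cluster genes, which pattern the body axis behind the forebrain, 2 of 39 were open, Hoxa7 (5.44 and 1.37) and Hoxc5 (1.76 and 0.615). Among factors of the midbrain, hindbrain and spinal cord only Pax5 and Pitx3 were open of 26, and Atoh1, a cerebellar granule cell factor, was closed. Of the monoaminergic and cholinergic list, whose neurons have their cell bodies outside the hippocampus, Dbh and Tph2 were open of 14 genes, and Chat, the acetylcholine synthesis gene, was closed. No hepatocyte gene of 24 was open, 1 of 23 striated muscle genes was (Mylpf), 2 of 21 male germ cell genes were (Zpbp and Dazl), and 6 of 1135 olfactory receptor genes were. Set against matched random lists, the shares were 5.13% against 74.1% for Hox genes, 7.69% against 77.8% for midbrain, hindbrain and spinal cord factors and 0.529% against 9.70% for olfactory receptors (each at an adjusted permutation p of 0.000886). They were 14.3% against 48.0% for monoaminergic and cholinergic genes (0.00954), 0% against 21.1% for hepatocyte genes (0.00954), 4.35% against 30% for muscle genes (0.00413) and 9.52% against 37.0% for male germ cell genes (0.00496). A promoter window of 2000 bp ended the calls of the monoaminergic and cholinergic list (28.6%), the hepatocyte list (12.5%) and the muscle list (26.1%), with adjusted p over 6 alternatives of 0.00797 to 0.116, 0.000564 to 0.224 and 0.000564 to 0.538. Replicate 1 alone kept the calls at higher shares of 12.8% for Hox genes, 11.5% for midbrain, hindbrain and spinal cord factors, 21.4% for monoaminergic and cholinergic genes, 4.17% for hepatocyte genes and 0.881% for olfactory receptors. In replicate 2 alone, 8.70% of muscle genes and 0.969% of olfactory receptor genes were open, and both calls held. Hox and olfactory receptor genes stand in clusters, so both lists were also moved as a whole along the order of protein-coding genes, and at the other positions 54.2% of promoters were open on average for each (permutation p 0.001 and 0.0000912).

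Marker genes of interneurons, oligodendrocytes, vessels and choroid plexus were also open less often than matched genes, and so, by a narrow margin, were those of granule cells. Of the GABAergic interneuron list 4 of 24 were open (Sox6, Maf, Htr3a and Adarb2), and Sst and the interneuron factor gene Dlx1 had no promoter peak. Of the oligodendrocyte list, myelin-forming cells, 3 of 22 were open (Fa2h, Cnp and Myrf), while Mobp and Aspa were closed. No gene of the 22 for endothelium, pericytes and vascular smooth muscle was open, and Abcc9 had no peak in either replicate. Of the choroid plexus and ependyma list 3 of 16 were open (Enkur, Dynlrb2 and Foxj1), and Aqp1 was closed. The dentate gyrus granule cell list had 9 of 18 genes open, with Pdzd2 at 6.51 and 3.39, Maml2 open in replicate 2 only and Dsp closed. The shares were 16.7% against 60.4% for interneurons, 13.6% against 48.1% for oligodendrocytes and 0% against 49.0% for vascular cells (each at an adjusted permutation p of 0.000886), 18.8% against 43.5% for choroid plexus (0.0384) and 50% against 72.4% for granule cells (0.0492). Several of these calls rested on a library or setting. In replicate 1 alone the oligodendrocyte share was 45.5% against 54% and the call ended, the interneuron share was 37.5% and the vascular share 31.8%. The granule cell call ended in replicate 1 alone (61.1%), in replicate 2 alone (66.7%) and under 3 other alternatives (50% against 54.1% without CpG matching, 66.7% with the 2000 bp window and 72.2% with the longer peak lists). The longer peak lists ended the interneuron call at 50% and the oligodendrocyte call at 36.4%, and the choroid plexus call ended with the 2000 bp window (31.3%) and with basic transcript starts (18.8% against 41.4%). Adjusted p over 6 alternatives ran from 0.000827 to 0.439 for oligodendrocytes, from 0.0236 to 1.00 for granule cells, from 0.000886 to 0.0849 for interneurons and from 0.00564 to 0.232 for choroid plexus.

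For the other 15 lists the share of open promoters was not distinguishable from random lists. Of excitatory hippocampal neuron genes 16 of 20 were open, with Lingo1 (2.43 and 0.975) and Emx1 (1.76 and 0.788) among them, while genes with a peak in replicate 1 only included Slc17a7, the vesicular glutamate transporter gene, Sv2b and Rtn4r (80% against 63.3%, adjusted permutation p 0.154). In replicate 1 alone all 20 were open (100% against 71.3%) and the list was above random, as it was with the 2000 bp window (90%), without CpG matching (80% against 54.2%) and with the longer peak lists (95%), with adjusted p over 6 alternatives from 0.000775 to 0.274. The CA1 list had 50% open, with Wfs1 open and Fibcd1 and Dcn closed (0.624), and the CA2 and CA3 list 50%, with Grik4 open, Cacng5 in replicate 1 only and Iyd closed (0.624). The neurogenesis and immature neuron list had 61.1% open, with Sox4 and Top2a open and Dcx closed (0.180), and the forebrain regional factor list 54.2%, with Nfib and Nfix in replicate 1 only and Lef1 closed (0.395). The astrocyte list had 8 of 20 open, or 40% against 60.3% (0.0642), with Atp1b2 open, Aldh1l1 open in replicate 1 only and Aqp4 closed. That list depended on the library and on the calling threshold: replicate 1 alone had 90% open against 67.4%, above random, and replicate 2 alone 45%, while the longer peak lists gave 85% open in both against 66.7% (adjusted permutation p 0.0806). Basic transcript starts gave 30%, below random, with adjusted p over 6 alternatives from 0.00715 to 0.35. The microglia list had 3 of 22 open, Irf8 among them (13.6% against 32.1%, 0.0530), and was below random in replicate 1 alone (18.2%), in replicate 2 alone (13.6% against 32.8%) and without CpG matching (13.6% against 54.4%), with adjusted p over 6 alternatives from 0.00109 to 0.381.

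Lists of signalling and clock genes were open at high shares without passing the test. The long-term potentiation and CREB list had 31 of 36 genes open (86.1% against 72.9%, adjusted permutation p 0.0676), with Itpr1 open, Adcy1 in replicate 1 only and Grin2d closed. It was above random in replicate 1 alone (94.4%), in replicate 2 alone (88.9%), with the 2000 bp window (94.4%), without CpG matching (86.1% against 54.1%) and with the longer lists (97.2%), with adjusted p over 6 alternatives from 0.000564 to 0.267. All 19 circadian clock genes were open (0.0530), and the list was above random with basic transcript starts and without CpG matching (100% against 81.0% and 54.1%), with adjusted p over 6 alternatives from 0.000564 to 0.206. All 11 genes of the X-inactivation escape list were open, Xist (1.63 and 0.660), Jpx and Mid1 included (0.180), and without CpG matching the list was above random (100% against 54.1%), with adjusted p over 6 alternatives from 0.00248 to 0.417. Of the imprinted list 65.9% were open, Usp29 and Inpp5f among them, and Asb4 was closed (0.188). The oligodendrocyte precursor list had 4 of 14 open (Pdgfra, Vcan, Lhfpl3 and Tnr; 28.6%, 0.262), with Bcas1 in replicate 1 only and Cspg4 closed, and 57.1% in replicate 1 alone. Of erythroid and lymphoid genes Lck and Pax5 were open (8.33% against 24.2%, 0.0676), of keratinocyte genes Grhl1, Krt10 and Krt77 (15% against 20.7%, 0.720), and of photoreceptor and lens genes Gnat1 and Opn1sw (10% against 30%, 0.0564). Without CpG matching all of these last 3 lists were below random, each against 54% to 54.4%, and with basic transcript starts the blood cell and photoreceptor lists, at 0%, were below random as well, with adjusted p over 6 alternatives from 0.000564 to 0.268, 0.00131 to 1.00 and 0.000827 to 0.173.

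**Figure D2:**
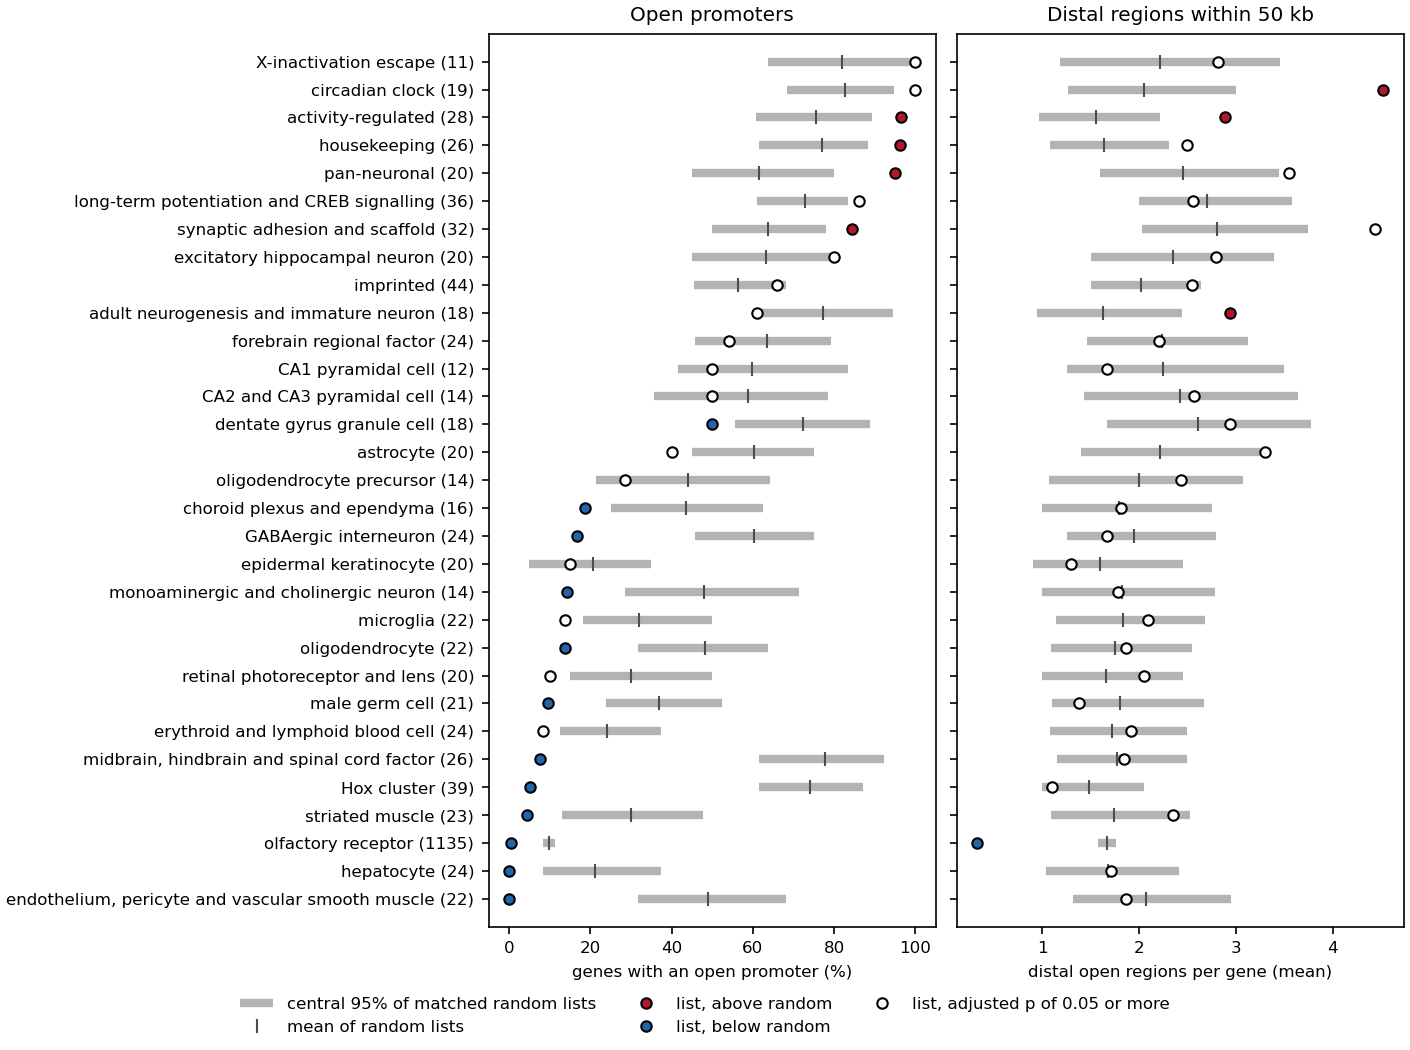
Share of genes with an open promoter (left) and mean number of distal open regions per gene within 50 kb (right) for 31 gene lists, with the number of genes in brackets, filled points for lists that passed the test, and grey bars for the central 95% of 10000 matched random lists. Pan-neuronal genes lie at 95% and Hox genes at 5.13% on the left, and circadian clock genes at 4.53 regions per gene on the right.

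Distal open regions, which lie outside the promoter windows, were more numerous near clock genes and genes of recent neuronal activity than near length-matched genes. The neurogenesis and immature neuron list passed the test too, but most alternatives ended that call. Per1 (chromosome 11, 69095217 to 69109960) had 12 shared distal regions within 50 kb and Nr1d1 (chromosome 11, 98767932 to 98775333), which encodes a clock repressor, had 11. Borcs6, with 16, lies within 50 kb of Per1, so the regions cannot be credited to Per1 alone. Random lists were not matched on gene density. Among activity-regulated genes Btg2 and Fosb had 8 each, and in the neurogenesis list Sox4 had 7, Top2a 6 and Dcx 1. Around the 1135 olfactory receptor genes there was a mean of 0.328 regions, though Olfr263 and Olfr1368, neighbours on chromosome 13, had 9 each, and a region near several genes counts for each of them. Against random lists matched on gene length the mean number per gene was 4.53 against 2.05 for clock genes (adjusted permutation p 0.0418), 2.89 against 1.55 for activity-regulated genes (0.0217), 2.94 against 1.63 for the neurogenesis list (0.0418) and 0.328 against 1.67 for olfactory receptors (0.00620; 1.88 for the list moved along the order of genes, permutation p 0.0000912). In replicate 1 alone the means were 8.42 against 3.74 for clock genes, 5.57 against 2.82 for activity-regulated genes and 0.495 against 3.06 for olfactory receptors, and these calls held. The neurogenesis call ended in replicate 1 alone (4.72 against 2.96), in replicate 2 alone (3.39 against 2.05), without length matching (2.94 against 1.88) and with the longer peak lists (4.39 against 2.69), with adjusted p over 5 alternatives from 0.00207 to 0.131. Without length matching the activity-regulated call ended (2.89 against 1.88), with adjusted p over 5 alternatives from 0.00207 to 0.0824.

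The other 27 lists did not differ from length-matched lists, though single neuronal and glial genes, some of them very long, had high counts. Their means ran from 1.1 for Hox genes to 4.44 against 2.81 for the synaptic list (adjusted permutation p 0.102), where Cntnap2 and Dlg2 had 13 each. Rbfox1 had 15 and Rbfox3 had 8, Lingo1 10, Grik4 9, Pdzd2 9, Aldh1l1 10, Atp1b2 7, Itpr1 8 and Nfib 11. These counts for single genes are not corrected for gene length. Per 100 kb of gene and flanks, Cntnap2 (2244.86 kb long) had 0.554, Dlg2 (1972.58 kb) 0.627 and Rbfox1 (1526.17 kb) 0.922. The shorter genes Lingo1 and Atp1b2 had 3.60 and 6.59. Some genes with closed promoters had distal regions near them, such as 5 for the CA1 marker Fibcd1, 4 for Sst, 5 for the myelin gene Mobp, 6 for the microglial receptor gene Cx3cr1 and 7 for the endothelial factor gene Erg. The synaptic list was above random in replicate 2 alone (7.66 against 4.13) and without length matching (4.44 against 1.87), with adjusted p over 5 alternatives from 0.0248 to 0.110. In replicate 1 alone the forebrain regional factor list, at 2.21 against 2.23 in both, was above random at 11.6 against 4.05, with adjusted p over 5 alternatives from 0.0351 to 0.857. Tcf4, chosen after its values were seen, held 126 of the 279 distal peaks there and the other 23 genes 153. Across the genome Gm20388, an annotated gene that spans 4434.88 kb, had the most distal regions (90), followed by Fgfr2 (41, annotated over 2960.9 kb). Next were Btn2a2 (22), Asic2 (21) and Camta1 (19), then Gse1 (17, with a promoter peak in replicate 1 only). Borcs6, Hist1h2bh, Hist1h3f and Hist1h3g had 16 each. The histone genes and Btn2a2 lie close together on chromosome 13, and Gse1 lies within Gm20388, so their windows overlap and their counts share regions.

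Some binding motifs were several times as frequent at distal open regions as in the flanking sequence. Among them were those of CTCF, which shapes chromatin loops, and of NeuroD, RFX, NFI, EGR and CREB. Other motifs did not differ from the flanks or were less frequent at the regions. The CTCF motif lay in 22.4% of 21589 windows of 200 bp, against 0.264% of windows 1000 bp away, 85 times the share. The NeuroD-type E-box, bound by neuronal basic helix-loop-helix factors, was found in 5.73% against 0.926%, a ratio of 6.19. The RFX X-box stood at a ratio of 20.2, NFI at 10.1, EGR at 8.35, CRE, bound by CREB, at 5 and AP-1 at 1.33. The McNemar exact test, adjusted over 32 motifs, placed 17 motifs above the flanks, the others being NRF1 (14.7, from 44 windows against 3, 95% interval 4.70 to 73.8), REST (11, from 11 windows against 1, 1.60 to 473), YY1 (4.42), SP/KLF (2.54), the glucocorticoid receptor (2.11), the CAGCTG E-box (1.94), ETS (1.61), the CACGTG E-box (1.42), STAT (1.32) and NFY (1.27). The share of regions with CTCF grew with signal, from 7.60% in the weakest signal quintile to 37.3% in the strongest, while NFI went from 1.39% to 0.457%.

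For several motifs the result turned on the choice of background. The regions had 51.2% GC and the flanks 45.2%, and the GC-matched windows differed from the flanks in position as well as in GC content. Below the flanks were GATA (0.532), ZBTB18 (0.556), MEF2 (0.559), homeobox (0.641), T-box (0.695) and FOX (0.875). With random windows matched on GC content, MEF2 (1.43), homeobox (1.48) and FOX (1.24) were above background instead, IRF, which had not differed (0.890), was above at 1.29, and YY1 was below at 0.502. GC matching ended the calls of ETS (1.39), NFY (1.00), STAT (1.29) and ZBTB18 (0.682), put the POU octamer above background at 1.41, and lowered the ratios of CRE to 2.84, EGR to 3.84, NRF1 to 6.29, NFI to 6.28 and SP/KLF to 1.54. No difference from the flanks was found for SOX, ROR, PBX/MEIS, TEAD, PU.1, HNF4A, HNF1, POU or IRF. With windows of 100 bp the calls of REST (7.00, from 7 windows against 1, 95% interval 0.899 to 315) and ZBTB18 (0.556) ended, and IRF was below at 0.628. The ratios rose to 146 for CTCF, 45.0 for RFX (90 windows against 2, 95% interval 12.1 to 377), 18.1 for NFI, 10.9 for NeuroD and 7.5 for CRE.

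Single libraries moved several of these motif ratios. From the peaks of replicate 1 alone, REST stood at 53, NFI at 20.8, RFX at 10.9, NRF1 at 8.88, EGR at 5.29 and YY1 at 2.88, and the POU octamer (0.870), IRF (0.722), HNF4A (0.746) and ROR (0.714) were below the flanks. From replicate 2 alone, RFX stood at 31.0, EGR at 4.79 and YY1 at 2.66, the calls of NFY (1.11) and STAT (1.19) ended, and HNF1 (0.0909) and ROR (0.710) were below. TEAD was above the flanks in replicate 1 alone (1.1) and in replicate 2 alone (1.14).

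**Figure D3:**
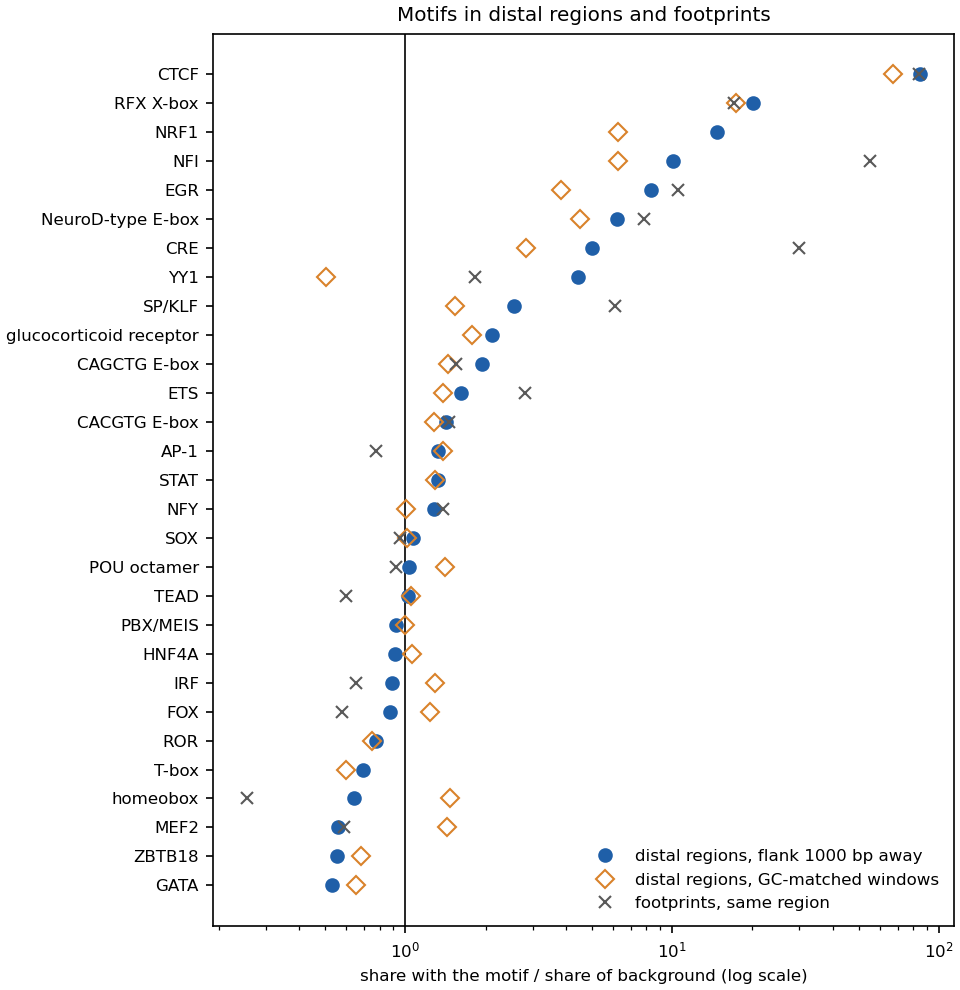
Share of windows with each motif divided by the share of background windows (x axis, log scale) for distal regions against flanks 1000 bp away (circles), distal regions against GC-matched windows (diamonds) and footprints against the same region (crosses). CTCF stands at 85 against flanks, and MEF2 lies at 0.559 against flanks and at 1.43 against GC-matched windows.

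Footprints, short stretches that DNase I spares where proteins sit, were tested for motifs in all shared regions, promoters included. Promoter windows held 36.0% of all footprints of replicate 1 and 38.9% of those of replicate 2. Many motifs above the flanks at distal regions were also above background in footprints, but distal footprints were not tested apart. Replicate 1 had 236942 footprints with a median width of 10 bp and replicate 2 had 159538 with a median width of 9 bp, and 70.5% and 70.6% lay in peaks of the same library. By an overlap of 50% of the shorter footprint, 28.3% of the footprints of replicate 1 were found in replicate 2 and 45.7% the other way. Inside peaks these shares were 36.0% and 55.5%, against 16.6% and 22.9% for footprints placed at random in any peak of the same library. These placements did not keep a footprint in its own peak and included peaks of a single library. The gap therefore does not separate agreement of footprint positions from sharing of peaks. CTCF lay in 253 footprint windows against 3 background windows of the same region (ratio 84.3, 95% exact binomial interval 28.5 to 412), CRE in 120 against 4 (30, 11.4 to 112), NFI in 55 against 1 (55, 9.47 to 2211.38) and RFX in 34 against 2 (17, 4.36 to 146), so the order of these ratios is not settled. Ratios were 10.6 for EGR, 7.83 for the NeuroD-type E-box and 6.09 for SP/KLF. Footprints where a CTCF site may also count as the NeuroD-type E-box were not removed. ETS (2.81), the CAGCTG E-box (1.55), the CACGTG E-box (1.46) and NFY (1.38) were above background too, and NRF1 lay in 0.704% of footprints and in no background window. The homeobox motif (0.255) and GATA (0.111, from 1 window against 9, 95% interval 0.00253 to 0.802) were below background, but the footprint windows had 62.8% GC and the background windows 57.2%. Among the 1167 pairs of windows of similar GC content no motif was below background, with homeobox in 1 footprint window against 2, and CTCF (16 windows against 1, 95% interval 2.49 to 671), NeuroD (19 against 2, 2.29 to 84.1) and SP/KLF (66 against 22) were still above. The calls of CRE (8 windows against 1), EGR (12 against 3), ETS (13 against 6), the CAGCTG E-box (37 against 27), NFY (15 against 11), the CACGTG E-box (11 against 10), NRF1 (8 against 0), NFI (4 against 0) and RFX (2 against 0) ended in these pairs, which differ from the full set in GC content and in number. The McNemar exact test, adjusted over 32 motifs, used the 12646 of 57226 shared footprints for which the region left room for a background window. In replicate 1 alone the ratios were lower, at 18.4 for CTCF, 5.72 for CRE, 5.23 for EGR, 4.13 for RFX, 3.75 for SP/KLF, 3.29 for NeuroD and 1.47 for ETS, and the homeobox (1.03) and GATA (0.5) calls ended, while FOX was below (0.586). In replicate 2 alone CTCF stood at 49.4 and RFX at 6.80, homeobox at 0.573, GATA at 0.200, FOX (0.505) and IRF (0.517) were below and YY1 (1.85) was above. With footprints that were not widened the NFY call ended at 0.906 and the GATA call at 0, and YY1 was above at 3.0. The ratios were then 195 for CTCF (585 windows against 3, 95% interval 66.4 to 948), 57.3 for CRE (172 against 3, 19.3 to 281), 16.1 for EGR, 12.4 for NeuroD and 10.9 for SP/KLF, and AP-1, MEF2, SOX, TEAD, the POU octamer and FOX were below background, at 0.0968 to 0.386.

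Chromosome X carried fewer and weaker open regions than any autosome. It had 5.60 shared regions per Mb, against a mean of 14.8 ± 2.70 (SD, n = 19) for the autosomes and a lowest value of 11.5 on chromosome 3. Median signal on X was 1.54 in replicate 1 and 0.713 in replicate 2, where the autosomes lay at 2.15 to 3.09 and 0.908 to 1.12. The gene Xist, whose RNA coats the inactive X chromosome (chromosome X, 103460366 to 103483254), was open in both replicates. Of 948 protein-coding genes on X 374 were open (39.5%), against 11516 of 20807 on the autosomes (55.3%), an odds ratio of 0.526 (Fisher exact test, two-sided, p 1.0e-21). Among autosomal genes matched on CpG decile 44.7% were open (central 95% of draws 42.2% to 47.2%), so the share on X was lower after matching as well (permutation p 0.0002, the smallest these permutations can give). Genes are not replicates, and there was no male sample for comparison.

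**Figure D4:**
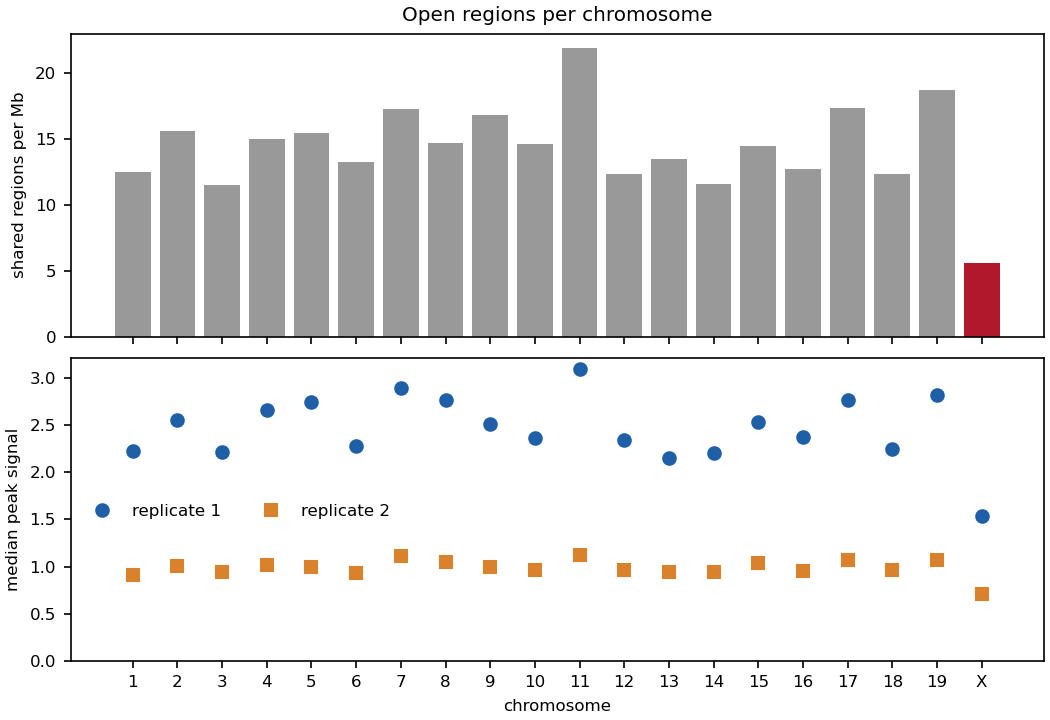
Shared open regions per Mb (top, bars) and median peak signal in replicate 1 (circles) and replicate 2 (squares) at shared regions (bottom) for each autosome and chromosome X. Chromosome X has 5.60 regions per Mb and medians of 1.54 and 0.713, each lower than on all 19 autosomes.

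Bases called by the rate of DNase I cuts covered 30.6 Mb in replicate 1 and 28.7 Mb in replicate 2 at a false discovery rate of 0.05, with 20.5 Mb in common and a Jaccard index of 0.529. At the stricter level of 0.001 the index was 0.544. Sites of the other library at 0.05 covered part of 58.4% of the peaks found in replicate 1 alone and 63.1% of those found in replicate 2 alone.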

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

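Tests of depth, of the longer peak list of replicate 2, of the share of tags in accessible sites and of the motifs of peaks found in a single library were chosen only after the results were seen, and the astrocyte list and the NFI motif were singled out from larger families in the same way, as were the genes named in this part; the readings of the tests of depth, of the calling threshold and of the distal log2 ratio were loosened from exclusions, and that of the share of tags from a fit, after their values were seen.

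Peaks and footprints were listed on chromosome Y although the labels give female mice, a signal in data that the comparisons leave out. Replicate 1 had 9 peaks and 42 footprints there and replicate 2 had 4 peaks and 10 footprints. None of these peaks overlapped an annotated gene, and 1 region of Y was shared by both libraries. No male sample was at hand for comparison, and the source of these calls was not tested.

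Replicate 1 had more peaks and footprints than replicate 2 and a higher signal at 96.5% of the shared regions. A difference in depth stays open: the size of the signal step would give tag totals with a ratio of 1.02 if both libraries were scaled alike, but the files state no scaling, so the value decides nothing. For the signal at shared regions a GC bias alone is argued against: the median log2 ratio was 1.1 in the lowest and 1.27 in the highest quintile of GC content. A constant offset from the unknown scaling would shift all quintiles alike, so only their small spread bears on GC. Peaks of a single library are outside this test, and their distal members had 52.6% GC in replicate 1 and 46.6% in replicate 2. A lower share of replicate 2 tags in accessible sites stays open for want of tag counts: replicate 1 was higher in at least 94.1% of regions in each of promoters, exons, introns and intergenic sequence, but this only splits the 96.5% by location and is no evidence for it. No biological explanation was tested because the design has 1 group.

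Promoters of the astrocyte list carried peaks more often in replicate 1, which had 18 of the 20 genes open, than in replicate 2, which had 9 (1 gene, Rorb, also stands in the clock list, and Gfap, open in both, had signal 6.85 and 1.58); Slc1a2, Slc1a3, Gja1, Aldoc, Aldh1l1, S100b, Fgfr3, Slc4a4, Acsbg1 and Gli3 were open in replicate 1 only and Gjb6 in replicate 2 only. Signal near the calling threshold in replicate 2 stays open: 55.6% of the promoters open in replicate 1 were not called in replicate 2, against 11.1% to 44.4% in random lists matched on replicate 1 signal (permutation p 0.0012, adjusted over 21 lists 0.0252), which had first been read as excluding it, but 8 of these 10 carried a peak in the longer list of replicate 2 (80%, against 65.2% of all protein-coding genes lost in this way), and matching on replicate 1 says nothing of signal in replicate 2. The shares were as high or higher for interneurons (55.6%), Hox genes (60%), oligodendrocytes (70%) and vascular cells (7 of 7), though these did not pass the adjusted test (0.172 to 0.526), so the pattern may not be particular to astrocytes. A different mix of cells in the tissue samples may be a candidate explanation. Distal peaks of replicate 1 only held the motif of NFI 8.83 times as often as peaks of replicate 2 only. The GC content of these peaks did not account for this (odds ratio within GC bins 8.16, 95% interval 5.37 to 12.4). NFI is a factor family active in astrocytes, but its genes Nfib and Nfix also stand in the forebrain factor list, so the motif does not single out astrocytes. Shared distal regions near the astrocyte list had a mean log2 ratio of 1.42, at the mean of 1.43 of matched random lists (permutation p 0.955), a gap within the spread of random lists (1.21 to 1.64) that decides nothing and was first read as an exclusion, and CTCF, used in all cell types, was also more frequent in peaks of replicate 1 only (odds ratio within GC bins 4.04), so a difference in preparation stays open and untested.

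Shared regions on chromosome X had lower signal than those on all 19 autosomes. Fewer CpG-rich promoters on X are argued against as the whole cause: among 374 open X genes the promoter signal was 0.544 times the autosomal median of the same CpG decile (95% interval 0.512 to 0.573; 0.511 in replicate 1 and 0.577 in replicate 2), while single autosomes set against the others lay between 0.887 and 1.11. Silencing of 1 X chromosome in female cells may be a candidate explanation: genes of the X-inactivation escape list, Kdm6a and Ddx3x among them, had a median promoter signal of 3.55, above the 0.99 to 2.0 of random lists of 11 of the other 367 open X genes (one-sided permutation p 0.0001, the smallest these permutations can give). Escape genes are also broadly active genes, which that test does not separate, and without a male sample the explanation stays a hypothesis. Pbdc1 and 5530601H04Rik had the same promoter signal (5.43 and 2.32 in replicates 1 and 2) and count as separate members. The list also holds long noncoding RNA genes such as Xist and Jpx, whereas the other 367 genes were protein-coding.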

How the results depend on the processing

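Only the alternatives with basic transcript starts, without olfactory receptor genes, with the longer lists for the correlation, without Tcf4, with footprint windows of similar GC content, with lists moved along the order of genes, and those on peaks of a single library were chosen after the results were seen. Of 1055 values under an alternative, 775 kept their side of the threshold or moved within their tolerance, where values past the test in neither setting were counted as kept even if their direction changed (astrocyte promoters with the longer peak lists, 85% open against 40%), 38 lost a call, 46 gained one, 185 moved and 11 reversed.

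With the longer peak lists there were 61152 shared regions, a Jaccard index of 0.398 and shares of 32.2% promoters, 30.3% introns and 31.4% intergenic sequence. The stronger 50% of each list gave 21395 regions, a share of 86.8% of replicate 2 peaks and an index of 0.517, and an overlap of 50% of both peaks gave shares of 50.7% and 61.8% for replicates 1 and 2. With the 2000 bp window the shares were 49.2% promoters, 3.44% exons, 20.8% introns and 26.5% intergenic, as wider promoters take regions from the others, and 7 lists were below random in open promoters. In single libraries the promoter share was 35.3% to 36.3%, exons 5.21% to 6.41%, introns 28.4% to 29.0% and intergenic 28.4% to 31.0%. Lists above random in open promoters numbered 5 to 7 in single libraries and 8 without CpG matching, and 2 lists were below random in distal regions without length matching. Motifs below the flanks numbered 8 to 10 in single libraries and 3 with GC-matched windows, and motifs below background in footprints 1 to 4 in single libraries, 7 without widening and 0 in the 1167 pairs of similar GC content, where 3 motifs were above.

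These results reversed: in replicate 1 alone, with replicate 2 alone in brackets, the astrocyte list stood at 90% open promoters (45%), forebrain factors at 11.6 distal regions (3.75), the POU octamer at 0.870 (1.06) and the homeobox in footprints at 1.03 (0.573). With GC-matched windows MEF2 stood at 1.43, homeobox at 1.48, FOX at 1.24, IRF at 1.29 and YY1 at 0.502, and without widening NFY in footprints at 0.906. The log2 ratio near olfactory receptors, 1.21, was above matched random lists but not past the test, and below the 1.40 of the list moved along the order of genes (permutation p 0.000729). The causes were not tested. In the forebrain list Tcf4 alone held 126 of the 279 distal peaks of replicate 1, but without it the mean of 6.65 stayed above the 3.53 of random lists that also lost their member with the most peaks (permutation p 0.001, not adjusted).

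The X chromosome odds ratio stayed between 0.468 and 0.527 over 4 alternatives. Ranking footprints by strength, to keep the stronger 50%, could not be done, because the deposited footprint value is constant. Depth is unknown, so it cannot be said which closed promoters would be called with more tags.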

Other observations

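All comparisons and named genes in this part were chosen only after the results were seen, and lists and motifs were singled out from families of 31 lists and 32 motifs.

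Replicate 1 held more stretches of densely packed peaks than replicate 2. Around Tcf4, a gene of a basic helix-loop-helix factor, 124 peaks of replicate 1 lay in 100 kb (chromosome 18, 69600001 to 69700000), 123 of them not found in replicate 2, which had 13 peaks there, 12 of them its own. Other such stretches held Nfic, Celf5, Ncln and S1pr4 (61 peaks against 11), Tmem150c (44 against 1), Hivep3 (44 against 3), and Znrf4, Safb2 and Safb (40 against 4). Stretches of 100 kb with at least 10 peaks of a single library numbered 110 in replicate 1, with 8.49% of its single-library peaks, and 3 in replicate 2, with 0.273%.

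Distal peaks near some lists were split unevenly between the libraries. Forebrain factors had 279 peaks in replicate 1 and 90 in replicate 2, 75.6% in replicate 1 against 56.6% in random lists (permutation p adjusted over 31 lists 0.00310), and 67.1% without Tcf4, outside the range of 49.4% to 61.9% of random lists that also lost their member with the most peaks of replicate 1. Hox and olfactory receptor genes stand in clusters where a peak counts for several genes: the sums over genes were 104 against 43 for Hox genes and 562 against 557 for olfactory receptors, but the different peaks numbered 18 against 8 (69.2% in replicate 1) and 232 against 223 (51%). For the lists moved along the order of genes, the shares by gene of 70.7% and 50.2% stood against 57.7% and 57.9% (permutation p 0.0299 and 0.000182, not adjusted), and for Hox genes this rests on few peaks. At shared distal regions the mean log2 ratio of replicate 1 to replicate 2 was higher than in random lists for Hox genes (2.24 against 1.71, adjusted permutation p 0.00620; 1.39 for the list moved along the order of genes, permutation p 0.000547), midbrain, hindbrain and spinal cord factors (1.71 against 1.37, 0.0413) and vascular genes (1.65 against 1.34, 0.0496). It was lower for activity-regulated genes (1.11 against 1.39, 0.0480) and long-term potentiation and CREB genes (1.13 against 1.39, 0.0413).

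Motifs differed between the 16736 distal peaks of replicate 1 only and the 10219 of replicate 2 only, in Fisher exact tests adjusted over 32 motifs. NFI lay in 2.25% against 0.254%, CTCF in 10.5% against 4.57%, and REST, which silences neuronal genes in other cells, in 95 windows against 0. AP-1 (3.88% against 8.03%), the NeuroD-type E-box (3.51% against 6.72%) and the RFX X-box (0.245% against 0.920%) were more frequent in replicate 2 only. Peaks of replicate 1 only had 52.6% GC and those of replicate 2 only 46.6%. Within bins of GC content the odds ratios were 4.04 for CTCF, 0.465 for AP-1, 0.565 for NeuroD and 0.183 for RFX, while the difference for MEF2 ended (0.898, 95% interval 0.759 to 1.06). Without the dense stretches the NFI ratio was 9.30.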
